A study of Mus musculus with 9 samples.

How the data were processed

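Bulk RNA sequencing of mouse tissue labelled as anterior paraventricular nucleus of the thalamus was analysed in 9 libraries, 3 each of non-stressed saline, stressed saline and stressed (2S,6S)-HNK (SHNK). Per the labels, RNA came from a Direct-zol kit, 100 ng of total RNA entered each library, and libraries were made with the SMARTer Ultra low RNA kit and TruSeq construction. The deposited table holds read counts per gene symbol, as whole numbers with no further normalization. Per the submitters' processing notes, Trimmomatic 0.38, HISAT2 and StringTie were used with GRCm38 and mm10. The role of each tool, the versions of HISAT2 and StringTie and the strandedness are not given in the sources used here. The table holds 18956 symbols, the lowest count is 1 and 0 symbols have a zero in any library. Of the symbols, 18333 (96.7%) match the RefSeq table for GRCm38.p6, which gave the coordinates.

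Groups were taken from the labels, and no library was left out of the reported fits. Replicate numbers are shared between groups, and a fit with them as a block was an alternative. Genes were kept with filterByExpr in edgeR on the groups (minimum count 10, minimum total 15), which left out 762 and kept 18194. Counts were scaled with TMM and fitted in 1 quasi-likelihood model over the 3 groups (glmQLFit and glmQLFTest in edgeR 4.0.16, R 4.3.3). The common biological coefficient of variation was 0.132. The adjusted p is the Benjamini-Hochberg value over all tested genes, with a threshold of 0.05. Log2 CPM used a prior count of 2. Total counts ran from 32307869 to 51569143 per library, so the spread between libraries, and not counting error, sets the precision for all but the least abundant genes.

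The comparisons were stressed saline against non-stressed saline, SHNK against stressed saline, and SHNK against non-stressed saline, with a test of any difference among the 3 groups. The log2 fold changes of the first 2 were also set against each other, beside 20 simulations with no effect that share the stressed saline libraries. The comparisons, their tests, the rule for named genes and the 38 gene lists were fixed before the data were examined, and what was chosen later is said where it stands. Lists were tested with camera in edgeR at a preset correlation of 0.01 (adjusted over the 38 lists) for lists with at least 3 tested members, again with an estimated correlation, and with fry. A member count is given over all genes and adjusted over the list alone.

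The lists covered activity (immediate early, secreted plasticity), GABA (GABA-A subunits, extrasynaptic GABA-A, other GABA synapse), H3K27 methylation, G-protein-coupled receptors, G protein subunits and regulators, glutamate receptors (ionotropic, metabotropic), synapse (postsynaptic density, presynaptic release), thalamic channels, mTOR and translation, glucocorticoid response and neuropeptides. Region lists were glutamatergic aPVT neurons, other thalamus, habenula, hippocampus, striatum and septum, and hypothalamus. Cell type lists were oligodendrocytes, their precursors, astrocytes, microglia, endothelium, mural cells and fibroblasts, choroid plexus, ependyma and cilia, and blood. The remaining lists were interferon and inflammation, chaperones, nuclear and mitochondrially encoded oxidative phosphorylation, cytosolic ribosome, nuclear noncoding RNA and sex-linked genes.

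Named genes followed a rule. It took the 10 largest rises and 10 largest falls per main comparison among genes past the threshold with a mean log2 CPM of at least 1 and groups that do not overlap (all if fewer), passing over unnamed gene models. It took 22 fixed genes in every comparison, for each called list 2 to 4 members with the smallest p in its direction, and up to 10 genes called with opposite sign in both main comparisons. It also took up to 4 members per list past 0.05 when adjusted over the list alone. Some genes that the rule names are not reported here. Alternatives were the DESeq2 1.42.0 test, limma 3.58.1 voom with sample quality weights, DESeq2 size factors or upper-quartile scaling in edgeR, no filter, a filter of 1 CPM in at least 3 libraries, the oligodendrocyte list mean as a covariate, a replicate block and a fit of the 2 compared groups only. Other thresholds (adjusted p of 0.1; unadjusted p of 0.05 with a 1.5-fold change) and leaving out each library were also run. The habenula list mean, alone or with the ependyma list mean, was added as a covariate after the data were seen. So was the removal of a spline trend on median transcript length and GC content (GENCODE transcripts; 16724 genes) from the log2 fold changes and from the signed z of each test, followed by cameraPR in limma on 37 lists.

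The pipeline was tested on simulated data with 18112 genes of which 200 were changed, in 2 runs. It recovered 71.9% of 2-fold and 54.8% of 1.5-fold changes with 3.12% false calls and called 0 unchanged lists. The simulated genes were drawn independently and the lists were random genes. The 0 therefore does not cover lists whose members vary together between libraries. Other splits of the real libraries gave up to 20 called lists.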

Results

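Bulk RNA was sequenced from tissue of the anterior paraventricular nucleus of the thalamus (aPVT), a midline thalamic nucleus rich in glutamatergic neurons, of BALB/c mice. The 9 libraries formed 3 groups of 3. They were non-stressed mice given saline, mice exposed to 5 days of social defeat and given saline, and defeated mice given (2S,6S)-HNK, a hydroxynorketamine metabolite of ketamine, called SHNK here. Social defeat exposes a mouse to an aggressive one. The labels do not say whether the 3 libraries of a group came from separate animals, so every p-value measures the spread between these libraries and nothing wider. Total counts were 45034669, 32307869 and 41237380 for non-stressed saline, 46189597, 44913532 and 34955518 for stressed saline, and 47039887, 51569143 and 38709827 for stressed SHNK. The count table held 18956 gene symbols, each with a count of at least 1 in all 9 libraries, and 18194 were tested. A gene silent in any library is therefore outside every comparison below.

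The composition of the libraries differed between the groups on gene lists fixed before the data were examined. In log2 CPM, counts scaled to a common library total, the mean over 15 genes enriched in the habenula, which borders this nucleus, was 3.45 ± 0.39 (SD, n = 3) in non-stressed saline. It was 5.05 ± 0.49 in stressed saline and 2.35 ± 0.21 in SHNK. The mean of 30 genes of ependyma and motile cilia, the lining of the ventricle, was 2.41 ± 0.14, 3.39 ± 0.27 and 2.58 ± 0.33 in the same order. For 30 astrocyte genes it was 7.40 ± 0.049, 7.44 ± 0.13 and 7.08 ± 0.020, and for 21 genes of other thalamic nuclei 6.65 ± 0.085, 6.48 ± 0.060 and 6.77 ± 0.045. Of these 21, 4 are also on another list. Among them is Calb2, the most abundant member of both this list and that of glutamatergic aPVT neurons. The habenula ranges did not overlap in any pair of groups, which for a single pair chance gives in 10% of splits of 3 against 3.

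**Figure D1:**
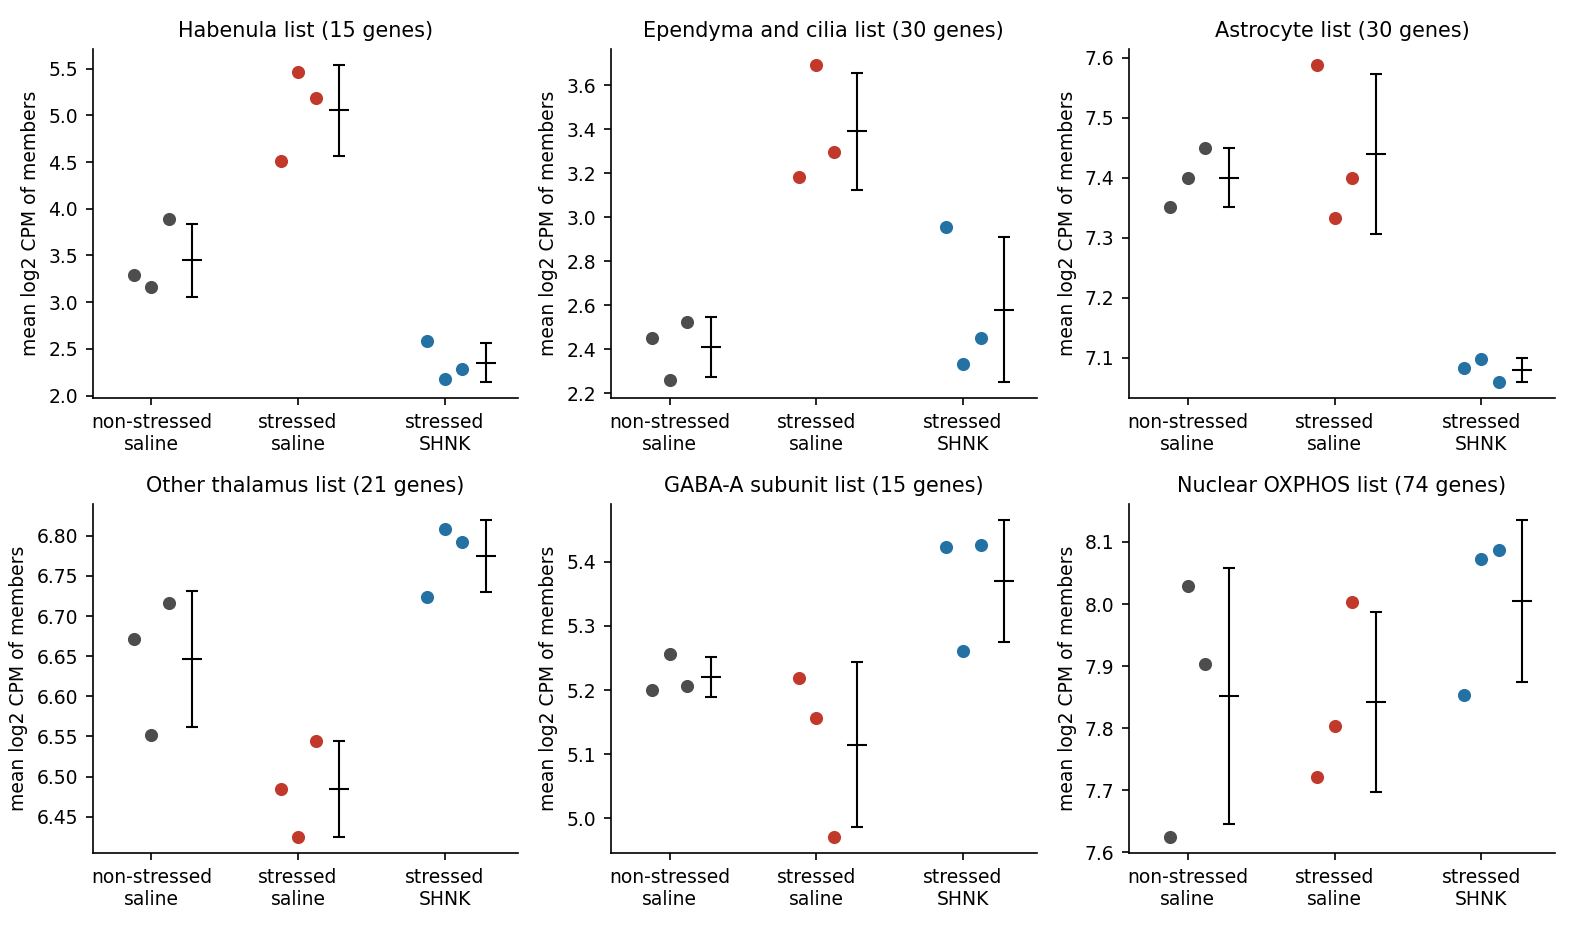
Mean log2 CPM of the members of 6 gene lists, each point a library (n = 3 per group), with the group mean and SD beside the points. The habenula list mean was 5.05 ± 0.49 in stressed saline and 2.35 ± 0.21 in SHNK, and the GABA-A subunit list mean 5.11 ± 0.13 and 5.37 ± 0.095.

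Stressed saline against non-stressed saline asked what social defeat did to the transcriptome of this tissue. Of 15 genes enriched in the habenula, 9 rose, 0 fell and 6 did not pass, and 14 rose when adjusted over the list alone. Camera gave adjusted p = 4.36e-35 (adjusted p = 0.0916 with an estimated correlation). Htr5b, which encodes a serotonin receptor, went from 7.85 ± 6.34 to 62.5 ± 31.7 CPM (SD, n = 3), a log2 fold change of 2.98 ± 0.48 (standard error; adjusted p = 0.00970). Tac2, the precursor of neurokinin B, rose by 3.07 ± 0.51 (adjusted p = 0.00970), and Pou4f1, a POU homeobox transcription factor, by 2.79 ± 0.56 (adjusted p = 0.0247). Gpr151, an orphan receptor of habenular neurons, rose by 1.67 ± 0.23 (adjusted p = 0.00532). Gpr151 passed in each of the 9 fits that left out 1 library. Tac2 (adjusted p = 0.0511, 0.0611 and 0.0518) and Pou4f1 (0.126, 0.112 and 0.157) missed the threshold without non-stressed saline replicate 1 or 2 or stressed saline replicate 2. Htr5b missed it without non-stressed saline replicate 1 or stressed saline replicate 2 (adjusted p = 0.0611 and 0.0518).

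The neuropeptide list was higher under stress too, in the libraries with the higher habenula mean (5.05 ± 0.49). Over all genes 4 of 32 members rose, with 5 up and 1 down when adjusted over the list alone. Of the 32, 21 are also on another list, so the rise is not independent of other lists. In camera the list had adjusted p = 0.0418 (adjusted p = 0.464 with an estimated correlation), a call lost without non-stressed saline replicate 1 or 3 or without stressed saline replicate 3 (adjusted p = 0.370, 0.0688 and 0.300). Tac1, the substance P precursor, rose by 0.92 ± 0.17, Adcyap1, which encodes PACAP, by 1.01 ± 0.16, and the prohormone convertase Pcsk1 by 1.09 ± 0.24 (adjusted p from 0.00970 to 0.0386). Tac1 missed the threshold without non-stressed saline replicate 1 or 2 or without stressed saline replicate 2 (adjusted p = 0.0621, 0.0502 and 0.0580), Adcyap1 without stressed saline replicate 2 (adjusted p = 0.0518) and Pcsk1 without non-stressed saline replicate 1, 2 or 3, stressed saline replicate 2 or 3 or without SHNK replicate 3 (adjusted p from 0.0565 to 0.154). The largest rises under the naming rule also included Nppa, the precursor of atrial natriuretic peptide (3.12 ± 0.37), Rspo4, a secreted enhancer of Wnt signalling (2.98 ± 0.42), and the synaptotagmin Syt15 (2.85 ± 0.34). Kcng4, a potassium channel subunit, rose by 2.74 ± 0.32, Klhl1 by 2.65 ± 0.40, the orphan receptor Gpr139 by 2.65 ± 0.40 and Nwd2 by 2.65 ± 0.44, the last a call lost without non-stressed saline replicate 1 or 2 or without stressed saline replicate 2 (adjusted p = 0.0602, 0.0611 and 0.0518).

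On the ependyma and cilia list 14 of 30 genes rose under stress, and 28 when adjusted over the list alone. The list's camera test gave adjusted p = 9.82e-59 (adjusted p = 0.0916 with an estimated correlation). Rsph1, a part of the radial spokes of motile cilia, went from 19.5 ± 1.49 to 42.2 ± 8.66 CPM (1.12 ± 0.15, adjusted p = 0.00532), and Ccdc153 and Tmem212, both markers of ependymal cells, rose by 1.17 ± 0.16 and 1.28 ± 0.20. The choroid plexus list was higher with 3 of 23 members up, and 7 when adjusted over the list alone. By camera the list had adjusted p = 2.62e-10 (adjusted p = 0.0916 with an estimated correlation). The 3 were Calml4 (1.19 ± 0.18), Lbp, which binds lipopolysaccharide (1.44 ± 0.28), and Sostdc1, a secreted antagonist of BMP and Wnt, which went from 2.06 ± 0.435 to 5.83 ± 3.15 CPM. Lbp missed the threshold without non-stressed saline replicate 1, 2 or 3 or without stressed saline replicate 2 (adjusted p = 0.0702, 0.114, 0.0510 and 0.131) and Sostdc1 without non-stressed saline replicate 1, 2 or 3, stressed saline replicate 2 or 3 or without SHNK replicate 3 (adjusted p from 0.0534 to 0.210). The log2 fold change of Sostdc1 was 0.97 without stressed saline replicate 2, and Tmem212 missed the threshold without non-stressed saline replicate 1 (adjusted p = 0.0511).

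Among astrocyte genes 2 of 30 rose, and 3 when adjusted over the list alone, while the list did not pass (camera adjusted p = 0.893). Gfap, the intermediate filament of astrocytes, rose by 1.51 ± 0.29 (adjusted p = 0.0181) and the water channel Aqp4 by 0.70 ± 0.13 (adjusted p = 0.0161). Gfap missed the threshold without non-stressed saline replicate 1 or 2 or without stressed saline replicate 2 (adjusted p = 0.0875, 0.0882 and 0.0911) and Aqp4 without non-stressed saline replicate 2 or without stressed saline replicate 2 (adjusted p = 0.0513 and 0.1004). On the hippocampus list Neurod1, a neuronal transcription factor, rose by 1.20 ± 0.25 and Rtn4rl2, a Nogo receptor homologue, by 2.46 ± 0.54. Neurod1 missed the threshold without non-stressed saline replicate 1, 2 or 3, stressed saline replicate 2 or 3 or without SHNK replicate 3 (adjusted p from 0.0516 to 0.133), and Rtn4rl2 without non-stressed saline replicate 1 or 2, stressed saline replicate 2 or 3 or without SHNK replicate 2 or 3 (adjusted p from 0.0520 to 0.266). They were 2 of 20 members, or 5 when adjusted over the list alone. Tested with camera, the list had adjusted p = 0.00229 (adjusted p = 0.167 with an estimated correlation). The oligodendrocyte list was higher, with 0 of 30 genes passing by edgeR over all genes or when adjusted over the list alone and 25 above 0 (1 at unadjusted p under 0.05, 0 by DESeq2 and 0 by limma voom). The camera test of the list gave adjusted p = 0.0180 (adjusted p = 0.717 with an estimated correlation), a call lost without non-stressed saline replicate 1 or 3 or without stressed saline replicate 1 or 3 (adjusted p = 0.279, 0.139, 0.151 and 0.737).

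**Figure D2:**
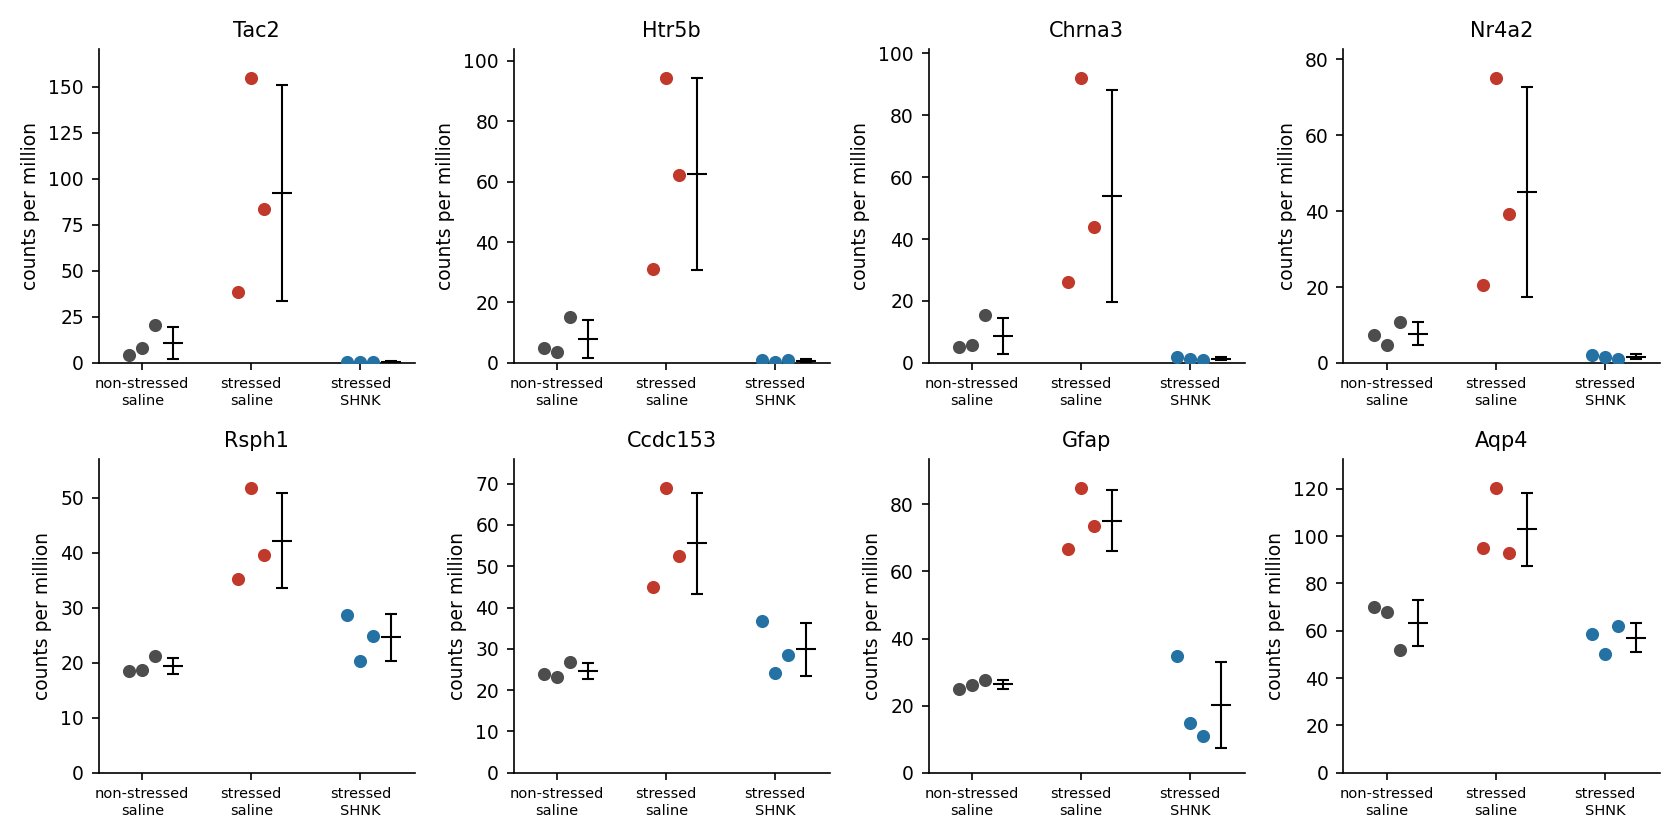
CPM of Tac2, Htr5b, Chrna3 and Nr4a2, of the ependymal genes Rsph1 and Ccdc153 and of the astrocyte genes Gfap and Aqp4, each point a library (n = 3 per group), with the group mean and SD. Tac2 stood at 92.4 ± 58.7 CPM in stressed saline and 0.508 ± 0.252 CPM in SHNK.

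The 3 genes that fell under stress included Dusp1 and Ptpn3. Dusp1, a MAP kinase phosphatase induced by activity and glucocorticoids, went from 64.5 ± 5.61 to 41.6 ± 4.80 CPM (fell by 0.63 ± 0.14, adjusted p = 0.0425). The tyrosine phosphatase Ptpn3 fell by 0.56 ± 0.12, adjusted p = 0.0349. Dusp1 missed the threshold without non-stressed saline replicate 1, 2 or 3, stressed saline replicate 1, 2 or 3 or without SHNK replicate 2 (adjusted p from 0.0502 to 0.164) and Ptpn3 without non-stressed saline replicate 1, 2 or 3, stressed saline replicate 1 or 2 or without SHNK replicate 2 or 3 (adjusted p from 0.0509 to 0.172). Other thalamic genes were lower as a list, with 1 of 21 down over all genes and 10 when adjusted over the list alone. The list had a camera adjusted p = 5.80e-06 (adjusted p = 0.137 with an estimated correlation).

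Synaptic lists were lower under stress, again in the libraries with the higher habenula mean. With edgeR, over all genes and when adjusted over the list alone, 0 members passed on the lists of the postsynaptic density (32 genes), presynaptic release (40), ionotropic glutamate receptors (29) and GABA-A subunits (15). At unadjusted p under 0.05 there were 7, 11, 5 and 3, by DESeq2 2, 1, 0 and 0, and by limma voom 0, 0, 0 and 0. Camera adjusted p values were 0.00187, 0.00228, 0.0166 and 0.0173 (adjusted p = 0.173, 0.111, 0.173 and 0.464 with an estimated correlation), and the GABA-A call was lost without non-stressed saline replicate 1 or without stressed saline replicate 3 (adjusted p = 0.0991 and 0.208). The extrasynaptic GABA-A list had 0 of 7 passing over all genes and 2 when adjusted over the list alone, Gabrd (-0.33 ± 0.11) and Gabrb2 (-0.25 ± 0.083), with 3 at unadjusted p under 0.05, 0 by DESeq2 and 0 by limma voom. For the list, camera gave adjusted p = 0.0180 (adjusted p = 0.173 with an estimated correlation), a call lost without non-stressed saline replicate 2 or without stressed saline replicate 3 (adjusted p = 0.0872 and 0.0549). Among metabotropic glutamate receptors 1 of 7 fell by either adjustment. Camera gave adjusted p = 0.0454 (adjusted p = 0.464 with an estimated correlation), a call lost without non-stressed saline replicate 1 or 3, stressed saline replicate 2 or 3 or without SHNK replicate 1 or 2 (adjusted p from 0.0574 to 0.434). Of 38 channels of thalamic excitability 0 passed over all genes (13 at unadjusted p under 0.05, 2 by DESeq2 and 0 by limma voom), and 1 was up and 1 down when adjusted over the list alone. In camera the list had adjusted p = 0.0348 (adjusted p = 0.464 with an estimated correlation), a call lost without non-stressed saline replicate 1 or 3 or without stressed saline replicate 2 (adjusted p = 0.134, 0.0688 and 0.104). The immediate early list was lower, with 1 of 39 down (Dusp1) and 1 up, the orphan nuclear receptor Nr4a2 (2.54 ± 0.40; not past it without non-stressed saline replicate 1 (adjusted p = 0.0536)), or 3 and 2 when adjusted over the list alone. The list's camera test gave adjusted p = 0.0207 (adjusted p = 0.464 with an estimated correlation), a call lost without non-stressed saline replicate 1 or without stressed saline replicate 1 (adjusted p = 0.0778 and 0.0522).

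None of the 22 genes fixed for every comparison passed here (edgeR adjusted p from 0.0706 to 0.992; 5 at unadjusted p under 0.05, 1 by DESeq2 and 0 by limma voom). Among GABA genes, log2 fold changes were -0.25 ± 0.11 for Gabra4 and -0.12 ± 0.11 for Gabra5. They were 1.05 ± 0.61 and 0.41 ± 0.28 for the GABA-synthesising enzymes Gad1 and Gad2. For the histone H3K27 demethylases Kdm6a and Kdm6b they were -0.12 ± 0.16 and 0.039 ± 0.18, and for the methyltransferases Ezh1 and Ezh2 0.11 ± 0.098 and 0.41 ± 0.20. Genes of aPVT neurons gave 0.037 ± 0.20 for Drd2, 0.086 ± 0.11 for Gal, 0.044 ± 0.12 for Calb2 and -0.12 ± 0.11 for the glutamate transporter Slc17a6. Activity genes gave -0.31 ± 0.30 for Fos, 0.37 ± 0.13 for Arc and -0.11 ± 0.11 for Bdnf. Stress-axis genes gave -0.16 ± 0.15 for Fkbp5, -0.35 ± 0.085 for Sgk1, -0.18 ± 0.072 for the glucocorticoid receptor Nr3c1 and -0.55 ± 0.26 for Crh.

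In total edgeR called 213 of 18194 genes under stress, 210 higher and 3 lower. The split was less one-sided at unadjusted p under 0.05 (1106 higher and 614 lower, or 754 and 135 with a 1.5-fold change), and DESeq2 called 438 higher and 34 lower. Camera called 18 of 38 lists, 7 higher and 11 lower, of which 0 held with an estimated correlation (smallest adjusted p = 0.0916), and fry called 4 of the 38. Of the 213 genes, 9 were on the habenula list and 14 on the ependyma list. All 213 had groups that did not overlap, against 12.9% of all tested genes and a chance share of 10%. With the habenula list mean as a covariate, a fit added after the data were seen, edgeR called 0 genes (883 at unadjusted p under 0.05; other tools were not run with it). The covariate separates the groups: the median absolute log2 fold change of the 213 genes went from 1.32 to 0.43, its median standard error from 0.24 to 0.46, and 41 of them took the opposite sign (58 with the ependyma mean as well). The count was 50 without non-stressed saline replicate 1, 71 without its replicate 2 and 40 without stressed saline replicate 2, against 472 by DESeq2 and 102 by limma voom. Of the 38 named genes past the threshold, 16 passed in all 9 fits that left out 1 library, and 20, 16 and 18 missed it without those 3 libraries in turn (highest adjusted p = 0.266). Of the 18 lists 10 were called in all 9 fits. With the trend on transcript length and GC content removed, also added after the data were seen, 4 of the 18 lost the call while their mean log2 fold changes kept their direction and at least 87.4% of their size. These were immediate early genes (mean -0.074 ± 0.084 to -0.087 ± 0.083, standard error over members; adjusted p = 0.0719) and metabotropic glutamate receptors (-0.12 ± 0.068 to -0.15 ± 0.063; 0.0804). The others were thalamic channels (-0.040 ± 0.047 to -0.054 ± 0.046; 0.116) and neuropeptides (0.17 ± 0.14 to 0.15 ± 0.14; 0.0629). On the 16724 genes of known length the last 3 missed it before the removal too (adjusted p = 0.0677, 0.0503 and 0.0777). The striatum and septum list gained a call, as higher (0.0504 before and 0.0284 after, mean 0.31 ± 0.13 to 0.29 ± 0.13).

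SHNK against stressed saline asked what the ketamine metabolite did in defeated mice. Of 15 habenula genes 10 fell, 0 rose and 5 did not pass, with 13 down when adjusted over the list alone. By camera the list had adjusted p = 4.93e-33 (adjusted p = 0.0620 with an estimated correlation). Tac2 went from 92.4 ± 58.7 to 0.508 ± 0.252 CPM (SD, n = 3; fell by 7.44 ± 0.70, adjusted p = 0.000187) and Htr5b fell by 6.34 ± 0.62, adjusted p = 0.000187. Chrna3, a nicotinic acetylcholine receptor subunit, fell by 5.23 ± 0.53, adjusted p = 0.000210, and Pou4f1 fell by 6.81 ± 0.79, adjusted p = 0.000570. Chat, the enzyme of acetylcholine synthesis, fell by 4.54 ± 0.84, adjusted p = 0.00861, but missed the threshold without SHNK replicate 2 or 3 (adjusted p = 0.0517 and 0.0568). The other large falls under the naming rule were those of Nppa (-6.15 ± 0.47), Nwd2 (-5.40 ± 0.53), Rtn4rl2 (-5.09 ± 0.67), Nr4a2 (-4.81 ± 0.46) and Scube1 (-4.59 ± 0.51).

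G-protein-coupled receptors were lower as a list, in the libraries with the lower habenula mean (2.35 ± 0.21). Of 103 receptors 13 fell and 4 rose, or 19 and 5 when adjusted over the list alone. Tested with camera, the list had adjusted p = 0.0116 (adjusted p = 0.457 with an estimated correlation). Their falls included Htr5b, Gpr139 (-3.53 ± 0.43), the somatostatin receptor Sstr2 (-2.16 ± 0.25) and Gpr151 (-2.11 ± 0.23). The hippocampus list had 5 of 20 members down, and 7 when adjusted over the list alone, among them Cabp7 (-1.96 ± 0.33) and Fibcd1 (-1.15 ± 0.18). The camera test of the list gave adjusted p = 3.78e-05 (adjusted p = 0.0620 with an estimated correlation). With the trend on transcript length and GC content removed, the mean log2 fold change (standard error over members) of the receptor list went from -0.30 ± 0.095 to -0.18 ± 0.094 (adjusted p from 0.0244 to 0.195). That of the hippocampus list went from -0.77 ± 0.27 to -0.57 ± 0.27 (0.000358 to 0.0547), so both calls were lost as the means shrank.

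On the astrocyte list 12 of 30 fell with SHNK and 0 rose, and 18 fell when adjusted over the list alone. The list had a camera adjusted p = 2.51e-11 (adjusted p = 0.226 with an estimated correlation). Gfap went from 75.1 ± 9.16 to 20.3 ± 12.8 CPM (fell by 1.89 ± 0.29, adjusted p = 0.00393) and Aqp4 fell by 0.85 ± 0.13, adjusted p = 0.00371. Sox9, a glial transcription factor, fell by 0.66 ± 0.11, adjusted p = 0.00525, and Clu, the secreted chaperone clusterin, fell by 0.47 ± 0.078, adjusted p = 0.00496. The ependyma and cilia list had 14 of 30 down and 29 when adjusted over the list alone, among them Rsph1 (-0.78 ± 0.15) and Ccdc153 (-0.89 ± 0.16). Rsph1 missed the threshold without SHNK replicate 2 or 3 (adjusted p = 0.0575 and 0.0578) and Ccdc153 without SHNK replicate 3 (adjusted p = 0.0568). For the list, camera gave adjusted p = 5.06e-19 (adjusted p = 0.226 with an estimated correlation). The choroid plexus list was lower with 4 of 23 down, or 6 when adjusted over the list alone. Camera gave adjusted p = 0.0107 (adjusted p = 0.375 with an estimated correlation), a call lost without SHNK replicate 2 (adjusted p = 0.0876). Oligodendrocyte precursor genes were lower, with 0 of 20 passing over all genes with edgeR (8 at unadjusted p under 0.05, 2 by DESeq2 and 3 by limma voom) and 5 when adjusted over the list alone, among them Olig1 (-0.30 ± 0.097) and Olig2 (-0.34 ± 0.11). In camera the list had adjusted p = 0.00743 (adjusted p = 0.375 with an estimated correlation). The precursor list mean went from -0.20 ± 0.052 to -0.089 ± 0.047 with the trend on transcript length and GC content removed (adjusted p = 0.0147).

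Of the 15 GABA-A receptor subunits tested, 4 rose with SHNK, 0 fell and 15 lay above 0, and 5 rose when adjusted over the list alone. The list's camera test gave adjusted p = 7.89e-06 (adjusted p = 0.226 with an estimated correlation). Gabra4 (chromosome 5, 71569734 to 71658308 on GRCm38), a subunit of extrasynaptic receptors in the thalamus, went from 226 ± 21.4 to 353 ± 45.3 CPM (0.64 ± 0.11, adjusted p = 0.00496). Gabrb2 (chromosome 11, 42419515 to 42632591) rose by 0.62 ± 0.083 (adjusted p = 0.00134). Gabrd (chromosome 4, 155384979 to 155398098), the delta subunit that mediates tonic inhibition, rose by 0.53 ± 0.11 (adjusted p = 0.0141). The extrasynaptic list, whose 7 members are all on the subunit list, had 3 up by either adjustment. By camera the list had adjusted p = 5.28e-05 (adjusted p = 0.0620 with an estimated correlation). Gabra4 and Gabrb2 passed in all 9 fits that left out 1 library, whereas Gabrd missed the threshold without stressed saline replicate 2 or without SHNK replicate 2 or 3 (adjusted p = 0.0623, 0.0675 and 0.0736).

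Gabra5 (0.19 ± 0.11) did not pass with SHNK, nor did Gad1 (-0.16 ± 0.58) or Gad2 (0.15 ± 0.28). Among other GABA synapse genes, 2 GABA-B receptor auxiliary subunits changed by either adjustment, Kctd16 (0.54 ± 0.11) and Kctd8 (-1.06 ± 0.20), and 22 of 24 did not pass (camera adjusted p = 0.629). Kctd16 missed the threshold without stressed saline replicate 2 or without SHNK replicate 3 (adjusted p = 0.0602 and 0.0706) and Kctd8 without SHNK replicate 2 or 3 (adjusted p = 0.0590 and 0.0568), and Kctd8 stood at -0.68 without stressed saline replicate 2. In the same libraries the habenula mean was 2.35 ± 0.21 with SHNK and 5.05 ± 0.49 in stressed saline.

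**Figure D3:**
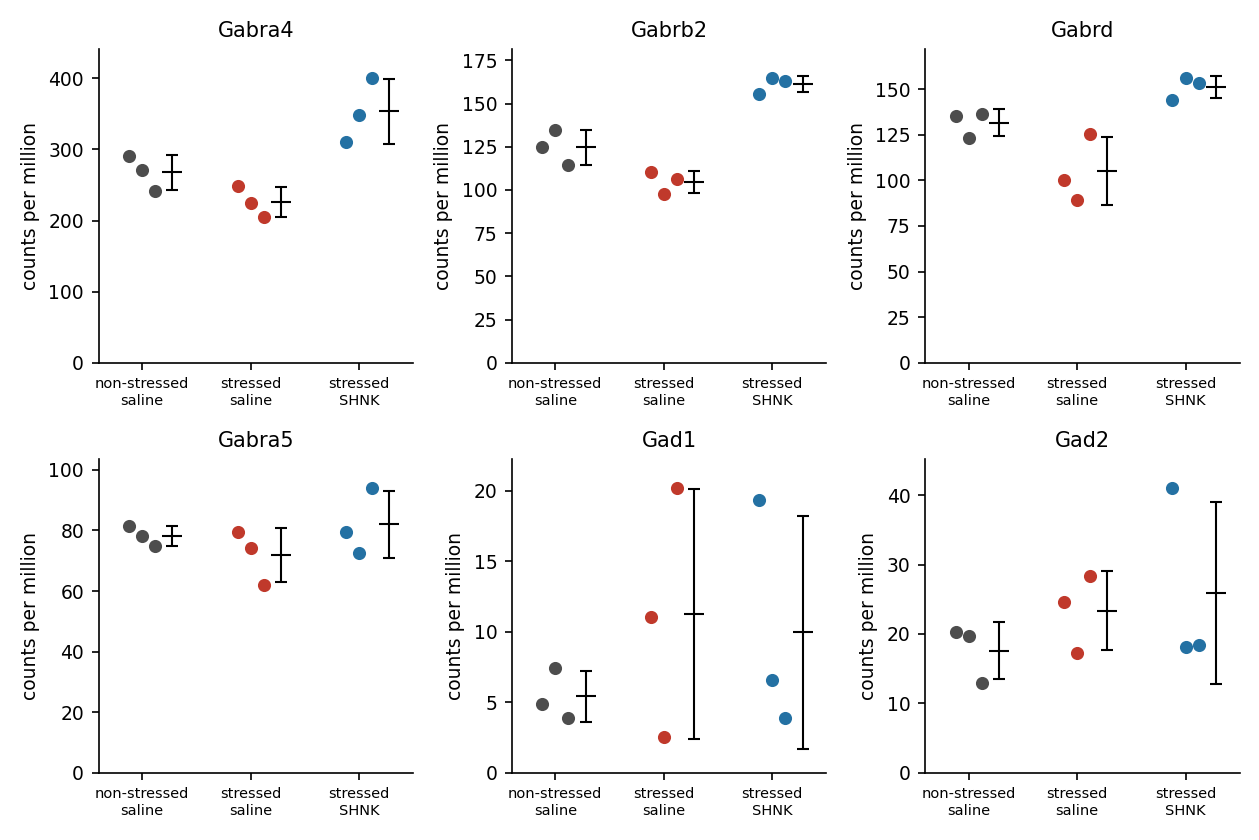
CPM of 4 GABA-A receptor subunits and of Gad1 and Gad2, each point a library (n = 3 per group), with the group mean and SD. Gabra4 stood at 268 ± 24.5 CPM in non-stressed saline, 226 ± 21.4 CPM in stressed saline and 353 ± 45.3 CPM in SHNK.

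In the same libraries, on the list of other thalamic nuclei 9 of 21 rose, and 12 when adjusted over the list alone. Tested with camera, the list had adjusted p = 3.19e-09 (adjusted p = 0.0620 with an estimated correlation). They included Ptpn3 (0.75 ± 0.12, adjusted p = 0.00455), Plekhg1 (0.62 ± 0.085), the calcium-binding protein Calb1 (0.59 ± 0.10) and the receptor-activity-modifying protein Ramp3 (0.55 ± 0.091). Among thalamic channels the potassium channel subunit Kcnab1 rose by 0.68 ± 0.11, the sodium channel Scn1a by 0.59 ± 0.098 and Kcnc2, a delayed rectifier, by 0.49 ± 0.085, while Kcnma1 fell by 0.78 ± 0.15, a call lost without SHNK replicate 3 (adjusted p = 0.0705). That list had 5 up and 2 down of 38, or 7 and 6 when adjusted over the list alone (camera adjusted p = 0.454).

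Glutamate receptors and release genes changed in single members with SHNK. The NMDA receptor subunit Grin2a rose by 0.44 ± 0.11. The AMPA receptor subunit Gria1 (-0.41 ± 0.079), the kainate receptor subunits Grik4 (-0.60 ± 0.11) and Grik5 (-0.54 ± 0.12) and Grm3 (-0.45 ± 0.10) fell. Grin2a missed the threshold without stressed saline replicate 1, 2 or 3 or without SHNK replicate 1, 2 or 3 (adjusted p from 0.0558 to 0.151), and Grm3 without stressed saline replicate 1 or 2 or without SHNK replicate 1, 2 or 3 (adjusted p from 0.0504 to 0.101). Gria1 missed it without SHNK replicate 3 (adjusted p = 0.0682), Grik4 without SHNK replicate 2 or 3 (adjusted p = 0.0565 and 0.0632) and Grik5 without stressed saline replicate 3 or without SHNK replicate 2 or 3 (adjusted p = 0.0550, 0.0712 and 0.101). The ionotropic list had 1 up and 3 down of 29 (2 and 3 adjusted over the list alone; camera adjusted p = 0.717). The metabotropic list had 1 up and 1 down of 7 (2 and 1; camera adjusted p = 0.259). Snap25 and Syt1, both part of the vesicle fusion machinery, rose by 0.52 ± 0.10 and 0.44 ± 0.074, and Snap25 missed the threshold without SHNK replicate 3 (adjusted p = 0.0570). On the presynaptic list 3 rose and 1 fell of 40 (3 and 2; camera adjusted p = 0.0666), and on the postsynaptic density list 1 and 1 of 32 by either adjustment (camera adjusted p = 0.943). With the trend on transcript length and GC content removed, the presynaptic list was called as higher (adjusted p from 0.0705 to 0.00259, mean log2 fold change 0.024 ± 0.043 to 0.14 ± 0.042).

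Secreted factors changed in single members. Igf1, an insulin-like growth factor, rose by 0.82 ± 0.14 (adjusted p = 0.00590) and the neuropeptide Cck by 0.81 ± 0.14 (adjusted p = 0.00639), while Nptx1, a neuronal pentraxin, fell by 2.37 ± 0.44 and missed the threshold without SHNK replicate 2 or 3 (adjusted p = 0.0524 and 0.0657). The secreted plasticity list had 3 up and 2 down of 23, or 5 and 4 when adjusted over the list alone (camera adjusted p = 0.460). Calca, which encodes CGRP, had the largest rise under the naming rule (22.5 ± 9.23 to 53.9 ± 13.6 CPM; 1.26 ± 0.26, adjusted p = 0.0146). The other large rises included Trim40 (1.08 ± 0.24), Sptssb, a subunit of serine palmitoyltransferase (1.06 ± 0.15), Krt12 (1.03 ± 0.25) and Smpx (1.01 ± 0.25). Endou (0.97 ± 0.18), Nexn (0.96 ± 0.13), Adm, the adrenomedullin precursor (0.93 ± 0.25), and Spp1, osteopontin (0.91 ± 0.16), were also among these 10. Calca (adjusted p = 0.0598, 0.0565 and 0.0935) and Trim40 (0.0798, 0.105 and 0.0971) missed the threshold without stressed saline replicate 2 or SHNK replicate 2 or 3. Krt12 (adjusted p = 0.108, 0.105, 0.0881 and 0.170) and Smpx (0.103, 0.0986, 0.114 and 0.147) missed it without stressed saline replicate 1 or 2 or SHNK replicate 2 or 3. For Endou the call was lost without SHNK replicate 2 or 3 (adjusted p = 0.0524 and 0.0526) and for Adm without stressed saline replicate 2 or 3 or without SHNK replicate 2 or 3 (adjusted p = 0.124, 0.109, 0.171 and 0.113), whereas Sptssb, Nexn and Spp1 passed in all 9 fits that left out 1 library.

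Stress-hormone and activity genes changed in single members too. On the glucocorticoid list 4 of 30 rose by either adjustment, and the list did not pass (camera adjusted p = 0.561). They were Dusp1 (0.71 ± 0.14), the kinase Sgk1 (0.44 ± 0.085), Tsc22d3, a glucocorticoid-induced leucine zipper (0.40 ± 0.091), and Nr3c1 (0.32 ± 0.072). Dusp1 and Sgk1 missed the threshold without SHNK replicate 2 (adjusted p = 0.0627 and 0.0573). Tsc22d3 (adjusted p = 0.0905, 0.0519, 0.0951 and 0.0791) and Nr3c1 (0.0880, 0.0508, 0.0793 and 0.0816) missed it without stressed saline replicate 2 or 3 or SHNK replicate 2 or 3. Arc, an immediate early gene of synaptic plasticity, fell by 0.82 ± 0.13, adjusted p = 0.00496. The immediate early list had 4 up and 2 down of 39 (5 and 2 adjusted over the list alone; camera adjusted p = 0.943). With the trend on transcript length and GC content removed, that list was called as higher (adjusted p from 0.852 to 0.0332), and its mean log2 fold change went from -0.14 ± 0.14 to 0.038 ± 0.14.

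The 16 fixed genes that did not pass with SHNK had adjusted p from 0.123 to 0.972. Beyond the GABA genes above, log2 fold changes were 0.026 ± 0.30 for Fos, 0.29 ± 0.11 for Bdnf, 0.039 ± 0.15 for Fkbp5 and 0.29 ± 0.26 for Crh. Genes of aPVT neurons gave -0.46 ± 0.20 for Drd2, 0.26 ± 0.11 for Gal, -0.19 ± 0.12 for Calb2 and 0.27 ± 0.11 for Slc17a6. H3K27 enzymes gave 0.16 ± 0.16 for Kdm6a, -0.24 ± 0.18 for Kdm6b, -0.15 ± 0.097 for Ezh1 and -0.41 ± 0.20 for Ezh2.

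In total edgeR called 1167 of 18194 genes with SHNK, 446 higher and 721 lower. At unadjusted p under 0.05 1927 were higher and 2320 lower, or 215 and 1009 with a 1.5-fold change. Camera called 15 of 38 lists, 7 higher and 8 lower, of which 0 held with an estimated correlation (smallest adjusted p = 0.0620), and fry called 10 of the 38. Of the 1167 genes, 10 were on the habenula list and 14 on the ependyma list. In 1162 of them the groups did not overlap, against 30.4% of all tested genes and a chance share of 10%. With the habenula list mean as a covariate, again added after the data were seen, edgeR called 0 genes (790 at unadjusted p under 0.05; other tools were not run with it). The median absolute log2 fold change of the 1167 went from 0.56 to 0.34, its median standard error from 0.12 to 0.44, and 429 of them took the opposite sign (307 with the ependyma mean as well). Under that covariate Tac2 went from -7.44 ± 0.70 to -1.46 ± 0.86, Gabra4 from 0.64 ± 0.11 to -0.084 ± 0.35, Gabrb2 from 0.62 ± 0.083 to 0.052 ± 0.28 and Aqp4 from -0.85 ± 0.13 to -0.83 ± 0.50. Tac2 is itself a member of the list behind the covariate, and the list mean separates the groups. These shifts therefore do not show that habenular tissue caused the changes. The count was 653, 367 and 718 without stressed saline replicate 1, 2 or 3 and 238 and 176 without SHNK replicate 2 or 3, against 2005 by DESeq2 and 2377 by limma voom. Of the 108 named genes past the threshold, 46 passed in all 9 fits that left out 1 library, and 38 missed it without stressed saline replicate 2 and 53 and 59 without SHNK replicate 2 or 3 (highest adjusted p = 0.251). Of the 15 lists 11 were called in all 9 fits.

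SHNK against non-stressed saline asked how far treated defeated mice stood from mice never defeated. The trend of log2 fold changes on transcript length and GC content had R2 = 0.196 here. It was 0.0783 for SHNK against stressed saline and 0.00497 for stress. The single gene past the threshold, named after its values were seen, was Mmp14, a membrane-bound matrix metalloproteinase, which fell by 0.75 ± 0.10 (n = 3 per group, edgeR adjusted p = 0.0477). Astrocyte genes were lower as a list, with 0 of 30 passing over all genes (18 at unadjusted p under 0.05, 12 by DESeq2 and 0 by limma voom) and 18 down when adjusted over the list alone. The camera test of the list gave adjusted p = 1.90e-14 (adjusted p = 0.370 with an estimated correlation). Aldh1l1, a folate enzyme used as an astrocyte marker, gave -0.62 ± 0.12 and Sox9 -0.53 ± 0.11. The habenula list was lower, with 0 of 15 passing over all genes (8 at unadjusted p under 0.05, 6 by DESeq2 and 0 by limma voom) and 6 when adjusted over the list alone, among them Tac2 (-4.37 ± 0.70) and Chrna3 (-2.60 ± 0.52). The list had a camera adjusted p = 5.62e-07 (adjusted p = 0.370 with an estimated correlation). GABA-A subunits were higher, with 0 of 15 passing over all genes (4 at unadjusted p under 0.05, 4 by DESeq2 and 0 by limma voom) and 4 when adjusted over the list alone. For the list, camera gave adjusted p = 0.00455 (adjusted p = 0.455 with an estimated correlation). Gabra4 gave 0.40 ± 0.11 and Gabrb2 0.37 ± 0.083. Their extrasynaptic part was higher with 2 of 7 up when adjusted over the list alone. Camera gave adjusted p = 0.0161 (adjusted p = 0.370 with an estimated correlation).

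Other thalamic genes were higher than in non-stressed saline, with 1 of 21 up when adjusted over the list alone, Calb1 (0.38 ± 0.099). In camera the list had adjusted p = 0.00621 (adjusted p = 0.370 with an estimated correlation), a call lost without non-stressed saline replicate 2 (adjusted p = 0.124). Ependyma and cilia genes were higher as a list with 0 of 30 passing by either adjustment (4 at unadjusted p under 0.05, 1 by DESeq2 and 0 by limma voom). The list's camera test gave adjusted p = 0.00657 (adjusted p = 0.690 with an estimated correlation), a call lost without non-stressed saline replicate 2 or without SHNK replicate 1 (adjusted p = 0.123 and 0.861). The mean log2 fold change of that list was -0.027 without SHNK replicate 1 and 0.18 with it. Postsynaptic density genes were lower, with 5 of 32 down when adjusted over the list alone, among them the scaffold proteins Shank3 (-0.56 ± 0.14) and Dlgap3 (-0.74 ± 0.18). By camera the list had adjusted p = 0.00595 (adjusted p = 0.370 with an estimated correlation). Oligodendrocyte precursor genes were lower, with 5 down and 1 up of 20 when adjusted over the list alone, among them Gpr17 (-0.55 ± 0.13). Tested with camera, the list had adjusted p = 0.00199 (adjusted p = 0.370 with an estimated correlation). The hippocampus list was lower with 3 of 20 down when adjusted over the list alone. The camera test of the list gave adjusted p = 0.0368 (adjusted p = 0.370 with an estimated correlation), a call lost without non-stressed saline replicate 1 or without SHNK replicate 2 or 3 (adjusted p = 0.0657, 0.113 and 0.0800). With the trend on transcript length and GC content removed, the mean log2 fold change (standard error over members) of the postsynaptic density list went from -0.16 ± 0.043 to -0.024 ± 0.030 (adjusted p from 0.00901 to 0.411). That of the hippocampus list went from -0.27 ± 0.15 to -0.077 ± 0.14 (0.0490 to 0.880, with the camera direction turned), so both calls were lost as the means shrank. The precursor list mean went from -0.22 ± 0.050 to -0.12 ± 0.032 (adjusted p = 0.00827) and that of other thalamus from 0.13 ± 0.035 to 0.20 ± 0.032 (adjusted p = 4.14e-05). The secreted plasticity list (adjusted p from 0.103 to 0.0133, mean 0.13 ± 0.083 to 0.19 ± 0.074) and the neuropeptide list (0.0988 to 0.0116, mean 0.0084 ± 0.16 to 0.063 ± 0.15) gained a call, both as higher. Without non-stressed saline replicate 3 the hippocampus mean was -0.17.

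None of the 22 fixed genes passed between SHNK and non-stressed saline (edgeR adjusted p from 0.0921 to 0.999; 4 at unadjusted p under 0.05, 4 by DESeq2 and 0 by limma voom). GABA genes gave 0.070 ± 0.11 for Gabra5, 0.20 ± 0.11 for Gabrd, 0.89 ± 0.60 for Gad1 and 0.56 ± 0.28 for Gad2. H3K27 enzymes gave 0.040 ± 0.16 for Kdm6a, -0.20 ± 0.18 for Kdm6b, -0.042 ± 0.098 for Ezh1 and 0.0014 ± 0.20 for Ezh2. Genes of aPVT neurons gave -0.42 ± 0.20 for Drd2, 0.35 ± 0.11 for Gal, -0.15 ± 0.12 for Calb2 and 0.15 ± 0.11 for Slc17a6. Activity genes gave -0.28 ± 0.30 for Fos, -0.45 ± 0.13 for Arc and 0.18 ± 0.11 for Bdnf. Stress-axis genes gave -0.13 ± 0.15 for Fkbp5, 0.093 ± 0.085 for Sgk1, 0.15 ± 0.072 for Nr3c1 and -0.26 ± 0.25 for Crh.

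In total edgeR called 1 gene here (3338 at unadjusted p under 0.05; DESeq2 994, limma voom 1). Camera called 14 of 38 lists, 8 higher and 6 lower, of which 0 held with an estimated correlation (smallest adjusted p = 0.370), and fry called 0 of the 38. With the habenula list mean as a covariate edgeR called 2 genes. The edgeR count was 0 with upper-quartile scaling, with no low-count filter, with a filter of 1 CPM, with the oligodendrocyte covariate and without non-stressed saline replicate 3 or SHNK replicate 1 or 3, 749 without non-stressed saline replicate 2, 8 without stressed saline replicate 1 or 2, 3 without SHNK replicate 2 and 2 without non-stressed saline replicate 1. Of the 14 lists 7 were called in all 9 fits that left out 1 library, and the cytosolic ribosome list turned from a mean log2 fold change of 0.079 to -0.032 without non-stressed saline replicate 1.

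The stress and SHNK changes were set against each other gene by gene. Of the 210 genes higher under stress, 171 were lower with SHNK. The 3 lower under stress, Dusp1 and Ptpn3 among them, were higher with SHNK, and 0 genes passed in the same direction in both edgeR tests. Those with the smallest summed ranks of p were Nppa, Nr4a2, Syt15, Kcng4, Gng8, a G protein gamma subunit, Gpr151, Cxcl11, a chemokine, Tex15, Cnmd and Wif1, a Wnt inhibitor. Kcng4 rose by 2.74 ± 0.32 and fell by 3.83 ± 0.35, and Wif1 rose by 1.69 ± 0.20 and fell by 1.58 ± 0.20. Independent lists of these sizes would share 8.32 and 0.0735 genes, but both comparisons use the same 3 stressed saline libraries with opposite sign. In 20 simulations with no effect and the same sharing, the highest count of opposite calls was 0. With no effect few genes can be called at all, so this 0 does not measure what the sharing adds. The 174 opposite calls became 30 without stressed saline replicate 2, 47 and 58 without non-stressed saline replicate 1 or 2, 113 without stressed saline replicate 3, and 77 and 66 without SHNK replicate 2 or 3, against 369 by DESeq2.

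Across the 18194 genes, which are not independent replicates, the covariance of the log2 fold changes was -0.0990. Simulations with no effect gave -0.0299 ± 0.000697 (SD, 20 simulations), and different stressed saline libraries for each comparison gave -0.0610 (6 choices, -0.0778 to -0.0409). The simulated genes were drawn independently, so they lack shifts that many genes share in a library. In 1 other split of the real libraries into 3 groups the covariance was -0.103. Pearson's r was -0.668 against a simulated -0.501, and Spearman's rho -0.456 against -0.460. The test of any difference among the 3 groups called 888 genes with edgeR (4000 at unadjusted p under 0.05), and 0 with the habenula covariate. The 888 became 187 and 508 without stressed saline replicate 2 or 3, 287 and 201 without SHNK replicate 2 or 3 and 1492 without non-stressed saline replicate 2, against 2102 by DESeq2 and 1824 by limma voom.

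**Figure D4:**
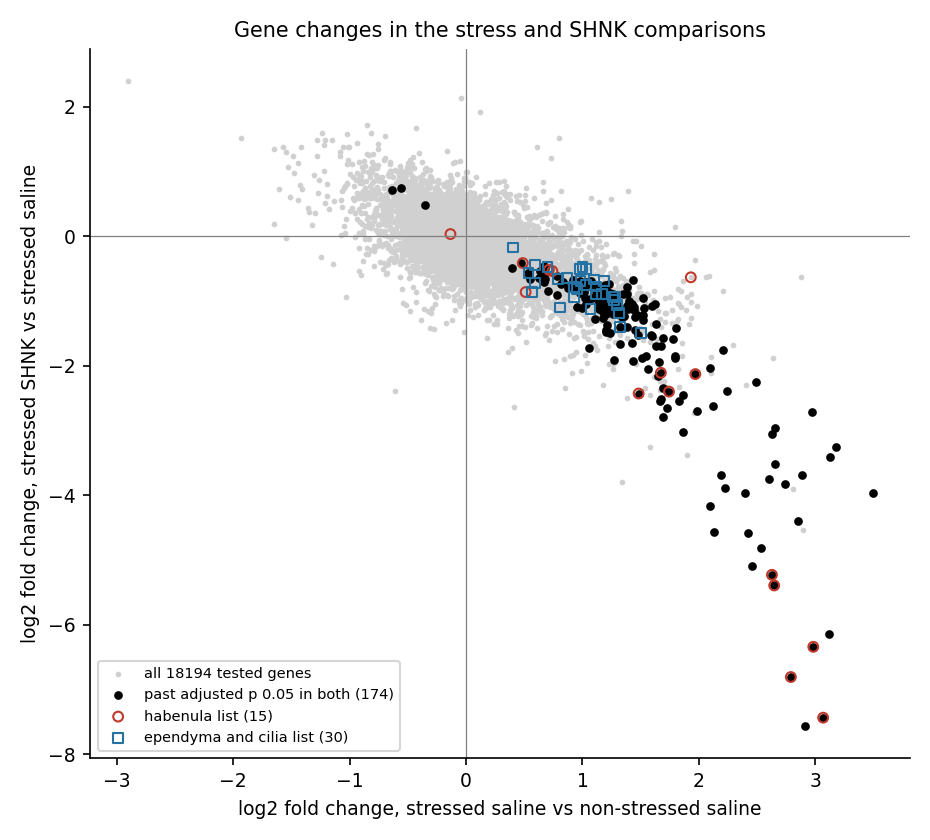
Log2 fold change of each of the 18194 tested genes under stress (horizontal axis) and with SHNK (vertical axis), with the 174 genes past the threshold in both in black and the members of the habenula (circles) and ependyma (squares) lists marked. Of the 174, 171 lie at lower right and 3 at upper left, and the covariance over all genes is -0.0990, against -0.0299 with no effect.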

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

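The fits with habenula or ependyma list means as covariates and the removal of the trend on transcript length and GC content were chosen after seeing the data, and all other alternatives before. Of 358 named results, 146 passed and 0 of these changed direction in the 18 alternatives run on them, which leave out the habenula covariates. The groups did not overlap for 213 of 213 genes called under stress and 1162 of 1167 with SHNK. Leaving out a library could hardly turn them, so this 0 says little. With the habenula mean as a covariate 41 of 213 genes called under stress and 429 of 1167 called with SHNK against stressed saline took the opposite sign, and 58 and 307 with the ependyma mean as well. Of 6442 values under alternatives 5857 kept direction and side of the threshold, 359 kept direction but lost the call, 191 gained one and 35 changed sign, in 18 results that did not pass. The 47 called lists gave 752 values, of which 602 kept the call, 148 lost it and 2 turned in camera's direction. These were the ribosome list without non-stressed saline replicate 1 and the hippocampus list (mean -0.077 with the trend on length and GC content removed), both for SHNK against non-stressed saline. The mean also changed sign for ependyma in that comparison (-0.027 without SHNK replicate 1) and for oligodendrocytes under stress (-0.00614 with their own mean as a covariate), both with the call lost. The cause was not tested for any change given here, except that fewer libraries and covariates that separate the groups leave less information per gene. Depth limits the least abundant genes: Pou4f1 stood at 0.0685 ± 0.0249 CPM in SHNK.

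With DESeq2 the counts of genes called were 472 (stress), 2005 (SHNK against stressed saline), 994 (SHNK against non-stressed saline) and 2102 (any difference), and 369 opposite calls. Limma voom gave 102 (stress), 2377 (SHNK against stressed saline) and 1824 (any difference). At an adjusted p of 0.1 they were 370, 2182, 520 and 1802, and 320 opposite calls. An unadjusted p of 0.05 with a 1.5-fold change gave 889, 1224, 597 and 1383. The habenula covariate gave 0, 0, 2 and 0 genes and 6, 8 and 9 lists, and with the ependyma covariate 0, 4, 4 and 4 genes and 7, 9 and 7 lists. For SHNK against non-stressed saline edgeR gave 9 in the fit of the 2 groups, beside the counts of 0 given above. With a replicate block it gave 6, against 177 for stress, 878 for SHNK against stressed saline and 685 for any difference, with 141 opposite calls and 16, 14 and 15 lists. Libraries of the same number correlated at -0.1002 to 0.106 in their deviations from group means, and 1 of 9 correlated best with its own number, so the numbers do not pair the libraries. Camera with an estimated correlation called 0, 0 and 0 lists, and fry 4 (stress) and 0 (SHNK against non-stressed saline). Removal of the trend on length and GC content gave 15, 15 and 14 lists, of which 14, 13 and 12 were called without it: 4, 2 and 2 lists lost the call and 1, 2 and 2 gained one. The covariance was -0.0610 with different stressed saline libraries and -0.0836 with the 1 CPM filter.

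Leaving out each library gave 40 to 306 genes for stress, 176 to 1385 for SHNK against stressed saline, 0 to 749 for SHNK against non-stressed saline and 187 to 1492 for any difference. Opposite calls ran from 30 to 233, the covariance from -0.134 to -0.0905, and called lists from 14 to 20, 13 to 17 and 12 to 16.

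Among named genes, and outside the habenula covariates, sign changes were in results that did not pass. Leaving out each library gave these lowest and highest log2 values. In stressed saline against non-stressed saline, Kdm6a ran from -0.25 to 0.057, Kdm6b -0.025 to 0.15, Drd2 -0.15 to 0.17, Calb2 -0.067 to 0.18, Slc17a6 -0.21 to 0.012 and Fos -0.59 to 0.028. For SHNK against stressed saline, Gad1 ran from -1.08 to 0.56, Gad2 -0.35 to 0.35, Kdm6a -0.017 to 0.29, Fos -0.35 to 0.25 and Fkbp5 -0.056 to 0.16. For SHNK against non-stressed saline, Gabra5 ran from -0.040 to 0.15, Gad1 -0.016 to 1.27, Ezh1 -0.11 to 0.023, Ezh2 -0.058 to 0.12, Fos -0.65 to 0.054, Fkbp5 -0.21 to 0.0085 and Crh -0.47 to 0.038. The cytosolic ribosome list, which passed in that comparison, had means from -0.032 to 0.20 when each library was left out. Under other alternatives for SHNK against stressed saline, limma voom gave 0.14 for Gad1, -0.000222 for Gad2, -0.0677 for Fos and -0.0502 for Fkbp5. For SHNK against non-stressed saline it gave -0.00129 for Gabra5 and -0.0114 for Ezh2. The oligodendrocyte covariate gave 0.671 for Gad1, and the replicate block -0.0187 for Fos, both against stressed saline.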

Other observations

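The tests of regulation within the sampled cells, of 1 habenular source over all 15 genes, and of transcript length and GC content for GABA-A subunits and receptors were chosen only after their results were seen. The test of astrocyte covariation replaced an earlier one that counted how many astrocyte genes were lower, and the number of splits into 3 groups was raised to 100 after fewer had been seen.

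Some genes on other lists differed with SHNK. Hba-a1, an alpha globin, rose against stressed saline from 120.1 ± 21.9 to 178 ± 10.8 CPM (0.57 ± 0.12, adjusted p = 0.0166, n = 3, edgeR), and 4 of 8 blood genes rose, or 5 when adjusted over the list alone. The list had a camera adjusted p = 3.95e-05 (adjusted p = 0.226 with an estimated correlation). Hba-a1 missed the threshold without stressed saline replicate 1 or 2 or without SHNK replicate 2 or 3 (adjusted p = 0.0532, 0.0707, 0.0701 and 0.0928). Dnaja1 and Hsp90aa1, both chaperones, rose by 0.41 ± 0.076 and 0.40 ± 0.082, and Bag3 fell by 0.78 ± 0.19 (3 up and 1 down of 33, 7 and 3 when adjusted over the list alone). For the list, camera gave adjusted p = 0.0452 (adjusted p = 0.375 with an estimated correlation), a call lost without stressed saline replicate 1 or 3 or without SHNK replicate 1 or 3 (adjusted p = 0.0681, 0.129, 0.0657 and 0.0850). Dnaja1 missed it without SHNK replicate 3 (adjusted p = 0.0531), Hsp90aa1 without stressed saline replicate 1 or without SHNK replicate 2 or 3 (adjusted p = 0.0504, 0.0575 and 0.0758) and Bag3 without stressed saline replicate 1 or 2 or without SHNK replicate 2 or 3 (adjusted p = 0.111, 0.0734, 0.113 and 0.148). Cycs, cytochrome c, rose by 0.44 ± 0.10 and the complex I subunit Ndufa10 by 0.39 ± 0.091, on an oxidative phosphorylation list with 5 of 74 up by either adjustment. Camera gave adjusted p = 1.68e-07 (adjusted p = 0.803 with an estimated correlation). Among the 10 splits of the libraries of both groups into 3 against 3, the real one ranked only 4 for this list. Its unadjusted camera p was 2.20e-08, against 4.27e-38 in another split. Cycs (adjusted p = 0.0857, 0.0719, 0.0754 and 0.122) and Ndufa10 (0.0859, 0.0959, 0.0786 and 0.125) missed the threshold without stressed saline replicate 1 or 2 or SHNK replicate 2 or 3. Of 77 ribosomal genes 0 passed by either adjustment with edgeR (4 at unadjusted p under 0.05, 0 by DESeq2 and 1 by limma voom). In camera the list had adjusted p = 0.0180 (adjusted p = 0.862 with an estimated correlation), a call lost without stressed saline replicate 1 or 2 or without SHNK replicate 2 or 3 (adjusted p = 0.376, 0.0807, 0.298 and 0.113). The interferon and inflammation list was lower, with 4 of 34 down, among them the MHC class I gene H2-D1 (-0.40 ± 0.099) and Irf7 (-0.77 ± 0.20), or 5 down and 1 up when adjusted over the list alone. The list's camera test gave adjusted p = 0.0389 (adjusted p = 0.457 with an estimated correlation), a call lost without stressed saline replicate 1 or 3 or without SHNK replicate 1 (adjusted p = 0.0741, 0.0678 and 0.0639). H2-D1 missed the threshold without stressed saline replicate 1, 2 or 3 or without SHNK replicate 2 or 3 (adjusted p from 0.0590 to 0.137) and Irf7 without stressed saline replicate 1 or 3 or without SHNK replicate 1, 2 or 3 (adjusted p from 0.0578 to 0.142).

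Under stress the interferon list was higher (0 of 34 over all genes with edgeR, 11 at unadjusted p under 0.05, 2 by DESeq2 and 1 by limma voom, 2 adjusted over the list alone, H2-D1 at 0.39 ± 0.099; camera adjusted p = 0.00105, adjusted p = 0.180 with an estimated correlation). The blood list was lower (0 of 8 over all genes, 4 at unadjusted p under 0.05, 0 by DESeq2 and 0 by limma voom, 4 adjusted over the list alone, Hba-a1 at -0.36 ± 0.12; camera adjusted p = 0.00482, adjusted p = 0.341 with an estimated correlation), and so were nuclear noncoding RNA genes (0 of 11 by either adjustment; 1 at unadjusted p under 0.05, 0 by DESeq2 and 0 by limma voom; camera adjusted p = 0.0188, adjusted p = 0.464 with an estimated correlation, lost without non-stressed saline replicate 1 or without stressed saline replicate 3 (adjusted p = 0.266 and 0.303)). Against non-stressed saline SHNK gave camera adjusted p = 0.0368 for blood (higher; adjusted p = 0.571 with an estimated correlation), lost without non-stressed saline replicate 3 or without SHNK replicate 3 (adjusted p = 0.132 and 0.125). It gave 0.00323 for chaperones (higher; adjusted p = 0.370 with an estimated correlation) and 3.24e-08 for oxidative phosphorylation (higher; adjusted p = 0.653 with an estimated correlation), the latter lost without non-stressed saline replicate 1 (adjusted p = 0.0629). Ribosomal genes had 0.00305 (higher; adjusted p = 0.826 with an estimated correlation), lost without non-stressed saline replicate 1 or without SHNK replicate 2 (adjusted p = 0.726 and 0.143). By unadjusted camera p the real split ranked 5 of 10 for oxidative phosphorylation and 7 of 10 for ribosomal genes. Noncoding RNA genes had 0.0413 (lower; adjusted p = 0.576 with an estimated correlation), lost without non-stressed saline replicate 1 or without SHNK replicate 2 (adjusted p = 0.219 and 0.155). Adjusted over the list alone, 0, 3, 0, 0 and 2 members of these 5 lists passed in the list's direction.

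Under stress, camera did not call 20 lists; those not yet given had adjusted p of 0.0666 (glucocorticoid response), 0.0666 (striatum and septum), 0.0776 (G-protein-coupled receptors), 0.0776 (microglia), 0.0956 (mTOR and translation), 0.246 (G protein subunits and regulators), 0.291 (glutamatergic aPVT neurons), 0.483 (secreted plasticity), 0.491 (mural cells), 0.577 (chaperones), 0.651 (oxidative phosphorylation), 0.689 (hypothalamus), 0.838 (mitochondrially encoded genes), 0.845 (cytosolic ribosome), 0.845 (sex-linked genes), 0.931 (other GABA synapse), 0.931 (H3K27 methylation), 0.931 (endothelium) and 0.941 (oligodendrocyte precursors). With SHNK against stressed saline, camera did not call 23 lists; those not yet given had adjusted p of 0.0740 (striatum and septum), 0.218 (oligodendrocytes), 0.259 (mitochondrially encoded genes), 0.285 (glutamatergic aPVT neurons), 0.318 (endothelium), 0.390 (hypothalamus), 0.537 (sex-linked genes), 0.561 (microglia), 0.561 (mural cells), 0.803 (H3K27 methylation), 0.864 (mTOR and translation), 0.943 (G protein subunits and regulators), 0.943 (nuclear noncoding RNA) and 0.987 (neuropeptides). With SHNK against non-stressed saline, camera did not call 24 lists; those had adjusted p of 0.0571 (choroid plexus), 0.0670 (immediate early genes), 0.0952 (secreted plasticity), 0.0996 (mTOR and translation), 0.125 (G-protein-coupled receptors), 0.137 (ionotropic glutamate receptors), 0.137 (neuropeptides), 0.162 (endothelium), 0.262 (mitochondrially encoded genes), 0.272 (G protein subunits and regulators), 0.272 (sex-linked genes), 0.515 (other GABA synapse), 0.515 (hypothalamus), 0.543 (thalamic channels), 0.543 (glucocorticoid response), 0.545 (microglia), 0.592 (striatum and septum), 0.680 (glutamatergic aPVT neurons), 0.764 (H3K27 methylation), 0.764 (presynaptic release), 0.764 (oligodendrocytes), 0.764 (interferon and inflammation), 0.853 (metabotropic glutamate receptors) and 0.853 (mural cells). Single members of these lists changed with SHNK against stressed saline: the striatal phosphoprotein Ppp1r1b fell by 1.26 ± 0.19, the tight junction gene Cldn5 fell by 0.54 ± 0.12, the smooth muscle gene Cnn1 fell by 1.78 ± 0.34 and Eef2k, a kinase of translation elongation, fell by 0.52 ± 0.12. Rheb, an activator of mTOR, rose by 0.45 ± 0.091, the phospholipase Plcb4 by 0.50 ± 0.089 and Rgs7, a regulator of G proteins, by 0.47 ± 0.082, while Ppp1r1b rose under stress by 1.17 ± 0.19, a call lost without non-stressed saline replicate 1 or 2 or without stressed saline replicate 2 (adjusted p = 0.0621, 0.0573 and 0.0518). Cldn5 missed the threshold without stressed saline replicate 3 or without SHNK replicate 3 (adjusted p = 0.0565 and 0.0909) and Cnn1 without SHNK replicate 2 or 3 (adjusted p = 0.0517 and 0.0568). Rheb missed it without stressed saline replicate 2 or without SHNK replicate 2 or 3 (adjusted p = 0.0518, 0.0502 and 0.0744) and Eef2k without stressed saline replicate 1 or 2 or without SHNK replicate 2 or 3 (adjusted p = 0.0758, 0.0815, 0.112 and 0.101). With the trend on transcript length and GC content removed, 5 of the lists not called were called, all as higher (given above). The test, mean and median of a list differed in sign for 0 called lists. They differed for other GABA synapse, H3K27 methylation, G protein subunits, hypothalamus and astrocytes under stress, and for immediate early genes, secreted plasticity, H3K27 methylation, thalamic channels, glucocorticoid response, neuropeptides and noncoding RNA with SHNK against stressed saline. With SHNK against non-stressed saline they differed for H3K27 methylation, metabotropic glutamate receptors, striatum, oligodendrocytes, microglia and mural cells.

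The habenula list mean was higher in stressed saline and lower in SHNK libraries than in non-stressed saline (for the latter 4 of 15 members lay above 0 and 0 passed with edgeR, 8 at unadjusted p under 0.05, 6 by DESeq2 and 0 by limma voom, and the list call was lost with an estimated correlation, adjusted p = 0.370), and the ependyma list mean was higher in stressed saline than in both other groups. Within groups the median correlation between habenula list members was 0.726, against a 95th percentile of 0.108 for 1000 random lists matched on expression, and between ependyma list members 0.620 against 0.0723, which is what unequal amounts of these tissues in the dissected pieces would give. Shared regulation of the genes on each list could give it too, since the random lists were matched on expression only. The ratio (non-stressed minus SHNK)/(stressed saline minus SHNK) in CPM had an interquartile range of 0.358 over the 15 habenula genes (0.0246 over the 10 that fell with SHNK, which that fall selected), so whether 1 habenular source was mixed in at a fixed ratio cannot be told apart from other causes, since the other 5, which did not pass with SHNK, gave ratios below 0. Genes called outside both lists followed the habenula mean within groups at a median correlation of 0.644 (187 genes higher under stress; exact permutation p = 0.00463 over all orders within groups, one-sided, the smallest they can give) and 0.439 (697 lower with SHNK; 0.00926), while for the 446 higher with SHNK it was -0.253 (0.0694), where habenular tissue and group cannot be told apart. Regulation of these genes by stress and SHNK cannot be told apart from tissue content either, since 0 libraries had a habenula mean within the range of another group, and of the 15 habenula genes 14 exceeded 1 CPM and 7 exceeded 10 CPM in non-stressed saline (Necab2 the most abundant at 336 CPM), with 6 also on another list (of 30 ependyma genes 29 and 8, Pltp at 160.3 CPM, and 1).

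GABA-A subunits were higher and G-protein-coupled receptors lower in SHNK libraries than in stressed saline. Within groups the correlation with the habenula mean was -0.204 for the GABA-A list mean (exact permutation p = 0.431, one-sided) and 0.0167 for the receptor list mean (0.491), so with 3 libraries per group habenular tissue and group cannot be told apart for either list. The GABA-A mean minus the other-thalamus mean differed by -0.0353 between SHNK and stressed saline libraries, with groups that overlapped, so a larger share of thalamic tissue in the SHNK pieces may account for the GABA-A rise. The list of glutamatergic aPVT neurons, which shares Calb2 with the other-thalamus list, was not called here (mean log2 fold change 0.035, camera adjusted p = 0.285). Removing the trend on transcript length and GC content left a mean log2 fold change of 0.260 ± 0.064 for GABA-A subunits (0.258 ± 0.058 before), which argues against these as the whole cause, and took that of the receptors from -0.295 ± 0.095 to -0.180 ± 0.094 with the call lost, where length and GC content cannot be told apart from other causes. Regulation of these genes by SHNK stays open and was not tested.

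Nuclear oxidative phosphorylation genes were higher and astrocyte genes lower in SHNK libraries than in stressed saline. Removing the trend on transcript length and GC content left a mean log2 fold change of 0.187 for oxidative phosphorylation (0.161 before; 0.102 without stressed saline replicate 1 and 0.246 without its replicate 3) and -0.276 for astrocytes (-0.358 before), which argues against these as the whole cause. Within groups the median correlation between astrocyte list members was 0.354, against a 95th percentile of 0.119 for 1000 random lists, so fewer astrocytes in the SHNK pieces may account for the second part. Shared regulation of astrocyte genes could give that correlation too, so the test cannot tell the 2 apart. All 30 astrocyte genes exceeded 10 CPM in non-stressed saline (Aldoc 2628 CPM), and 2 are on another list. The oxidative phosphorylation and ribosome means correlated within groups at 0.980 (exact permutation p = 0.00926, one-sided), as a shift shared by short abundant transcripts would give, and a change in metabolism or in astrocytes with stress or SHNK stays open, untested.

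Other splits of the same libraries were fitted. The 10 splits of 3 against 3 are too few for a share under 0.05. Stress gave 213 genes against a highest other of 0 (1 split as large, the real one included) and 18 lists against 17 (1), SHNK against stressed saline 1167 genes against 1 (1) and 15 lists against 20 (3), and SHNK against non-stressed saline 1 gene against 1 (2) and 14 lists against 20 (2). Of 100 splits into 3 groups, the real one included, 1 gave as many as the real 888 genes with any difference (highest other 458) and 1 as many as the real 174 opposite calls (highest other 1). Both are shares under 0.05. Such counts were therefore rare among other groupings of these libraries, but the splits do not test whether tissue content differed with group. No split kept the real groups with another of them as the shared one. For the covariance 2 of 100 were as extreme as the real -0.0990, a share under 0.05, and 1 other split was more extreme (-0.103).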
